A study of Homo sapiens with 12 samples.

How the data were processed

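Single cells of 12 cerebral organoids, 6 untreated and 6 exposed to 250 µM manganese for 48 h before collection at day 100, were profiled with a droplet 3′ RNA assay. Per the labels, organoids were dissociated with papain and DNase in the presence of an RNase inhibitor, actinomycin D and anisomycin, inhibitors of transcription and translation, and up to 10000 cells were captured per organoid. The deposited matrices hold raw counts of UMIs per gene and cell barcode, 1 matrix per organoid. Per the file headers and the submitters' processing notes, the authors made them with Cell Ranger 8.0.1 on GRCh38. The notes also list Seurat, with no role or version. Whether reads in introns were counted is not given in the sources used here. The matrices hold 38606 genes and 6444 to 14994 barcodes, more than 10000 in 6 libraries, and no barcode has under 500 UMIs. Every value was a whole count, and no column belonged to more than 1 sample. Of the mitochondrial genome only the 13 mRNAs are listed. Library totals ran from 57450033 to 114208578 UMIs, and 55371041 to 103957727 of them lay in kept cells. Pairs of libraries were checked for copies: over 66 pairs the closest had a chi-square of 98.6 per gene.

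Cells were kept with at least 1000 UMIs, at least 500 detected genes and at most 20% mitochondrially encoded UMIs. These limits removed 11175 barcodes for UMIs or genes and 347 for the mitochondrial share. Doublets were scored with Scrublet in scanpy, library by library. Where it called under 0.5% of a library, as in 10 libraries, the highest scores were removed at 0.4% per 1000 cells. In all 4112 doublets were removed, 0.555 to 5.35% of a library. Kept cells numbered 5615 to 13244 per organoid, with a median of 1780 to 2945 genes per cell.

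Kept cells of all organoids were clustered together with 2000 variable genes, 40 principal components, 15 neighbours and the Leiden method at resolution 1 (seed 1). Genes of the stress, metal, interferon, cytokine and mitochondrial lists were left out of the clustering, so that a response to manganese would not define a cluster. The 35 clusters were named from markers of 21 cell types fixed before the data were examined. A marker counted as detected in at least 10% of the cluster's cells, at 20 CPM or more and at 3 times the lower quartile over the clusters. A name needed at least 3 detected markers and a mean log2 ratio of the type's markers to that quartile of at least 2 (10 CPM added to both). It was withdrawn where the 10 leading genes held more markers of another type. Astrocyte and radial glia markers were merged into 1 astroglia class. Names such as choroid plexus-like therefore mean marker expression only. The 7 clusters without a name include 4 with TPH1 and RCVRN both among their 25 leading genes. That group was defined after the data were seen and tested as an added class.

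The organoid was the replicate, so p-values of the gene tests and permutation tests measure the spread between organoids, not between cells. Counts were summed per organoid over all cells and over each class. A library entered a class with at least 20 of its cells, and a class was tested with at least 4 libraries in each group. Choroid plexus-like and astroglia-like cells had 6 libraries per group, mesenchymal cell-like cells 4 and 4, and the TPH1 and RCVRN clusters 5 and 4. Genes were filtered with filterByExpr, normalised with TMM and tested with edgeR's two-sided quasi-likelihood F-test, with the size label and the treatment as terms. Adjusted p is Benjamini-Hochberg throughout, with a threshold of 0.05. CPM is the UMI count relative to the TMM-scaled library size, on the usual scale, log2 CPM uses a prior count of 2, and log2 fold changes are exposed minus untreated with the standard error of the fit. The same fit tested the size label, and a second fit tested the interaction of size and treatment.

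Before the data were examined, 25 gene lists were fixed, covering mitochondrial, interferon, sensing, stress, metal, metabolic and cell state genes. They were tested with camera in limma with a preset correlation of 0.01, two-sided, adjusted over all lists and classes together. Camera with an estimated correlation and fry were run beside it, adjusted in the same way. Camera compares a list's genes with the other genes. The preset correlation takes them as nearly independent, so its p does not measure the spread between organoids. The share of mitochondrially encoded UMIs, the class shares and the per-organoid difference of a list between choroid plexus-like and astroglia-like cells were compared with two-sided exact permutation tests of the difference in means. With 6 against 6 organoids there are 924 splits and the smallest p is 0.00216. The comparisons, tests, lists, cell filters and alternatives were chosen before the data were examined, apart from those said to have been added.

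Named genes followed a rule also fixed in advance. In each class it takes up to 10 genes each way with the largest fold change among those that pass and have a mean log2 CPM of at least 4, up to 4 members of each list with the smallest adjusted p, all mitochondrially encoded mRNAs, and a fixed set of sensing, interferon, metal handling and stress genes whatever their result. The text gives a part of these. Genes named for the size label, and markers and proteasome genes in the closing part, were chosen after their values were seen. XIST and Y-linked genes were left out.

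The fits were tested on simulated data: counts were drawn from a negative binomial distribution at the measured means, dispersions and library sizes of each class, with 200 genes changed by a known log2 fold change of 1 or 2. edgeR recovered 11% and 81% of them in all cells, 24% and 97% in choroid plexus-like cells, 5% and 76% in astroglia-like cells, 0% and 4.30% in mesenchymal cell-like cells, and 18% and 93% in the TPH1 and RCVRN clusters. DESeq2 recovered 44% and 94% in all cells and 26.3% and 90% in astroglia-like cells, with 51 and 33 unchanged genes called where edgeR called 4 and 7. In choroid plexus-like cells DESeq2 recovered 53% and 100%, with 47 unchanged genes called where edgeR called 8. A list shifted by 0.5 was called in all 5 sets of cells, with 2 other lists called in choroid plexus-like cells and none elsewhere. Genes were drawn independently of each other, so this cannot show how often lists are called wrongly where their genes move together. With edgeR most genes changed by a log2 fold change of 1 were missed in every set of cells.

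Alternatives fixed in advance were DESeq2, RLE factors in place of TMM, no filter on low counts, no size covariate, no mitochondrial limit or 10%, at least 2000 UMIs, doublets kept, the mitochondrial mRNAs removed before normalisation, Leiden resolution 0.5 or 2, the median over cells, permutation within the size labels, log odds of the class shares, and leaving out each organoid in turn. Added after the data were seen were the mean log2 CPM of cytosolic ribosomal protein genes as a covariate, the sets of libraries above and below the median of that level, a minimum of 100 cells per library, the size labels taken separately, clustering without the genes at an unadjusted p under 0.05, and leaving out organoids for the lists. Splits of the organoids into other groups of the same sizes were drawn at random, 40 per result where more exist. Gene spans came from the annotation, with long genes of at least 100000 bp and short genes of at most 10000 bp among genes of at least 1 mean CPM.

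Sequencing reads were not analysed here, and no correction for free RNA was applied. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (version 1.17.8).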

Results

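Cerebral organoids were grown from TMOi001-A, an established line of human induced pluripotent stem cells, and single cells were profiled at day 100 by droplet sequencing of transcript 3′ ends. An untreated group of 6 organoids (Con replicates 1, 4, 5, 12, 13 and 14) was compared with 6 organoids exposed to 250 µM manganese for 48 h (Mn replicates 3, 7, 8, 12, 20 and 21). Each group held 3 organoids labelled size S and 3 labelled size L. Manganese is an essential metal that is toxic to the nervous system in excess. The series title names double-stranded RNA transcribed in mitochondria and neuroinflammation, so the comparisons address mitochondrial transcripts, interferon and cytokine genes, and the stress programmes of each cell class. Counts of transcript 3′ ends measure mRNA levels and do not measure double-stranded RNA itself. The libraries held 57450033 to 114208578 UMIs (unique molecular identifiers, each a counted transcript) and 6444 to 14994 barcodes. After filtering, 114026 cells were kept, 59212 from untreated and 54814 from exposed organoids, with a median of 4092 to 8109 UMIs per cell across organoids.

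The first question was which cells the organoids held and whether manganese moved their shares. Choroid plexus-like cells, named by TTR, HTR2C, FOLR1 and other genes of the epithelium that secretes cerebrospinal fluid, made up 62836 cells in 14 clusters. Astroglia-like cells, named by SOX2, HOPX, FABP7, SPARCL1 and other genes of radial glia and astrocytes, made up 24394 cells in 8 clusters, with GFAP and AQP4 detected as markers in 6 of them. Smaller classes were excitatory neuron-like (3958 cells), mesenchymal cell-like (950 cells), Cajal-Retzius cell-like (794 cells) and dividing cell-like (691 cells). A further 14730 cells in 4 clusters carried general neuron markers such as STMN2 and SNAP25, but their leading genes matched the retinal marker list better, so they received no cell type name. They are called here the clusters led by TPH1, the first enzyme of serotonin and melatonin synthesis, and RCVRN, a photoreceptor calcium sensor, and they were singled out only after the data were seen. Choroid plexus-like cells made up 58.1 ± 34.4% of untreated and 51.8 ± 39.6% of exposed organoids (SD, n = 6 each), and astroglia-like cells 15.2 ± 21.3% and 21.8 ± 24.4%. Excitatory neuron-like cells made up 0.0677 ± 0.0797% and 7.56 ± 10.9%, with 2490 of the cells in Mn replicate 20 and 1156 in Mn replicate 8. Dividing cell-like cells made up 0.22 ± 0.340% and 1.02 ± 1.28%. Over the 7 classes no share passed the two-sided exact permutation test: the lowest p was 0.139, for dividing cells, and the lowest adjusted p was 0.50 over the 6 classes other than the TPH1 and RCVRN clusters, whose unadjusted p was 0.773. Composition varied so widely between organoids of one group that these differences lay within the spread between replicates.

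**Figure D1:**
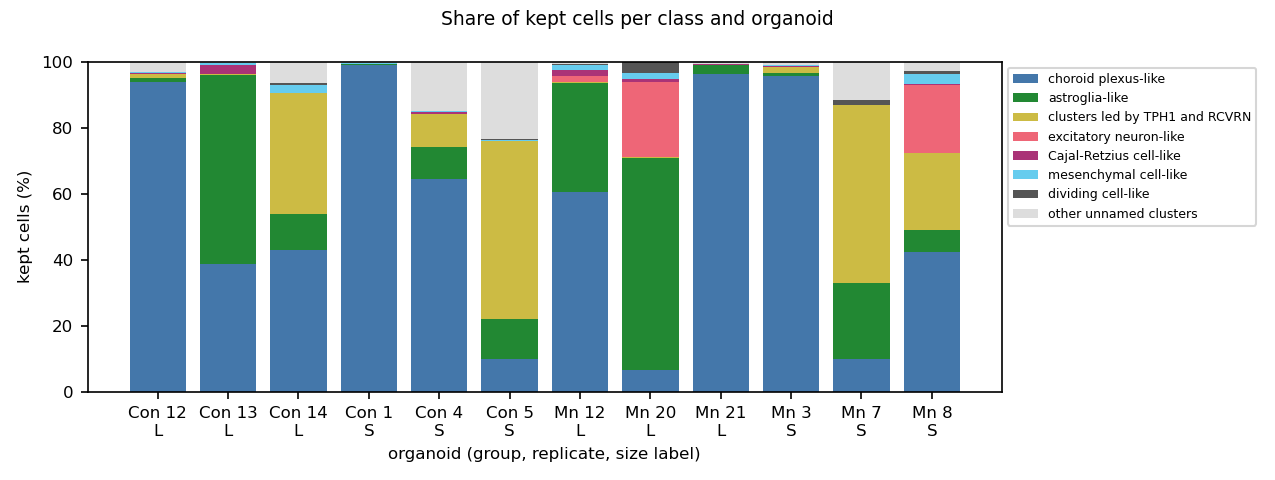
Stacked bars give the percentage of kept cells in each class (vertical axis, %) for each organoid (horizontal axis, with group, replicate number and size label). Astroglia-like cells range from 0.228% in Con replicate 1 to 64.4% in Mn replicate 20, and the grey part gathers the other clusters that received no name.

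The share of UMIs from the 13 mitochondrially encoded mRNAs, which code for core subunits of the respiratory chain, was higher in exposed organoids. Over all cells it was 1.49 ± 0.165% in untreated and 1.86 ± 0.189% in exposed organoids (SD, n = 6 each), a difference of 0.367 percentage points. All 6 exposed organoids lay above the untreated mean, and the two-sided exact permutation test gave p = 0.0108 and adjusted p = 0.0433 over 4 tests. Of single members, MT-ATP6, an ATP synthase subunit, was measured at 689 and 916 CPM (TMM-normalised UMI counts) and MT-CYB, of complex III, at 870 and 1111 CPM, and neither passed alone (edgeR adjusted p = 0.581 and 0.675). Within choroid plexus-like cells the share was 1.69 ± 0.375% and 2.35 ± 0.573%, higher in 5 of 6 exposed organoids, which missed the threshold (exact permutation adjusted p = 0.0606). In astroglia-like cells it was 1.25 ± 0.391% and 1.54 ± 0.328% (exact permutation adjusted p = 0.286), and in mesenchymal cell-like cells 1.06% and 1.25% (4 organoids each, exact permutation p = 0.714, where the smallest p possible is 0.0286). The libraries also split by their level of cytosolic ribosomal protein mRNA, a split seen in the data. The all-cell difference was 0.370 among the 6 libraries above the median level and 0.364 among the 6 below it. The choroid plexus difference was 1.25 and 0.0617 in the same sets. The all-cell call was lost without Con replicate 1 (0.398, adjusted p = 0.0519 by the exact permutation test), Con replicate 12 (0.336, 0.0866), Con replicate 13 (0.337, 0.0866) or Con replicate 14 (0.350, 0.0866). It was also lost without Mn replicate 3 (0.346, 0.0606), Mn replicate 7 (0.388, 0.0693), Mn replicate 8 (0.316, 0.0779) or Mn replicate 12 (0.341, 0.0693). The same test missed the threshold with no mitochondrial limit on cells (0.371, exact permutation adjusted p = 0.0693), with the median over cells (0.364, 0.0779) and when permuted within the ribosomal sets (0.367, 0.060). Without Mn replicate 21 the choroid plexus difference was 0.797 (exact permutation adjusted p = 0.0216) and without Con replicate 5 it was 0.788 (0.0433), so both passed.

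**Figure D2:**
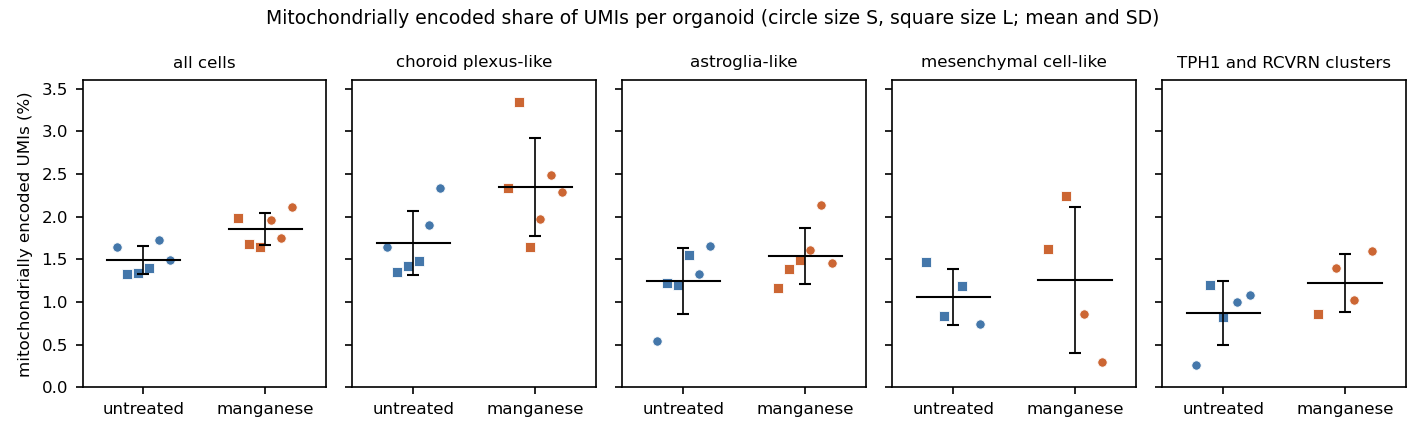
The vertical axis gives the percentage of UMIs from mitochondrially encoded mRNAs, with 1 panel for all cells and for each class, untreated organoids on the left and manganese-exposed organoids on the right. Each point is 1 organoid (circle size S, square size L), the line is the mean and the bar is 1 SD. Over all cells untreated organoids span 1.33 to 1.73% and exposed organoids 1.64 to 2.11%.

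The gene lists below were called by camera, and a call alone does not tell manganese from another grouping of the organoids. In all cells, astroglia-like and choroid plexus-like cells, adjusted over these alone, the real groups gave 31 list calls of 75. Other random splits gave a median of 32, and no such splits were drawn for lists of the other classes. Across all cells of each organoid, interferon-stimulated genes, the antiviral programme that type I interferon switches on, rose as a list in exposed organoids. Of 49 measured members 44 were higher, with a median log2 fold change of 0.82, and 6 of 6 exposed organoids lay above the untreated mean (camera adjusted p = 9.79e-13). The adjusted p was 0.789 with an estimated correlation. The chemokine CXCL10 was measured at 1.22 ± 1.01 CPM in untreated and 22.2 ± 36.4 CPM in exposed organoids (SD, n = 6 each). IFIT3 was measured at 4.97 ± 1.47 and 29.7 ± 46.0 CPM, and the ubiquitin-like modifier ISG15 at 17.1 ± 8.49 and 96.7 ± 171 CPM. No single one of these passed (edgeR adjusted p = 0.50 for CXCL10 and IFIT3 and 0.519 for ISG15), and Mn replicate 7 held much of the rise, since the list median was 0.43 without it. The RNA sensors RIGI (log2 fold change 0.86 ± 0.38 SE, edgeR adjusted p = 0.523) and IFIH1 (0.63 ± 0.33, 0.555), which detect double-stranded RNA, did not pass either.

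Mitochondrial gene lists also rose over all cells. The mitochondrial ribosome, which translates the mitochondrially encoded mRNAs, was higher in 44 of 51 members and 6 of 6 exposed organoids (median log2 fold change 0.26, camera adjusted p = 3.93e-06, or 0.799 with an estimated correlation). Nuclear genes of oxidative phosphorylation (OXPHOS) were higher in 58 of 73 members and 5 of 6 organoids (0.15, camera adjusted p = 0.00211, or 0.821 with an estimated correlation). The mitochondrially encoded mRNAs were higher in 12 of 13 members and 5 of 6 organoids (0.33, camera adjusted p = 0.0124, or 0.789 with an estimated correlation). Genes of at most 10000 bp had a median of 0.131 over all cells and genes of at least 100000 bp -0.207. The NRF2 list of oxidative stress genes rose (28 of 32 members, 6 of 6 organoids, 0.27, camera adjusted p = 0.000511, or 0.789 with an estimated correlation). So did proliferation genes (22 of 26, 4 of 6 organoids, 0.84, camera adjusted p = 0.0001) and reactive astrocyte genes (19 of 25, 4 of 6 organoids, 0.57, adjusted p = 0.0403). The adjusted p of these lists was 0.789 and 0.821 with an estimated correlation. The astrocyte filament GFAP was measured at 19.7 ± 38.4 and 145 ± 230 CPM (edgeR adjusted p = 0.620), with 572 CPM in Mn replicate 20 and 249 CPM in Mn replicate 12, and Mn replicate 20 held 64.4% astroglia-like cells and 368 of the 691 dividing cell-like cells. Hypoxia and glycolysis genes fell (30 of 41 members lower, 4 of 6 organoids, -0.26, camera adjusted p = 0.00333), as did heat shock genes (16 of 24, 4 of 6 organoids, -0.12, adjusted p = 0.0439). Their adjusted p was 0.821 and 0.799 with an estimated correlation. TRMT10C, a subunit of the enzyme complex that processes mitochondrial tRNA ends, was measured at 28.6 ± 5.51 CPM in untreated and 43.2 ± 9.45 CPM in exposed organoids and was higher in 6 of 6 (log2 fold change 0.59 ± 0.13, edgeR adjusted p = 0.50). NDRG1, a gene induced by low oxygen, was measured at 54.1 ± 23.8 and 19.98 ± 10.3 CPM and was lower in 6 of 6 (-1.33 ± 0.36, edgeR adjusted p = 0.50). PHGDH, the first enzyme of serine synthesis, was measured at 12.4 ± 4.43 and 23.6 ± 5.07 CPM (0.92 ± 0.23, edgeR adjusted p = 0.50). The signalling ligase TRAF6 was measured at 19.1 ± 4.04 and 11.9 ± 2.23 CPM (-0.68 ± 0.15, edgeR adjusted p = 0.50), and the metallothionein MT2A at 2371 and 1010 CPM (-1.35 ± 0.67, edgeR adjusted p = 0.543). Single libraries also moved the lists. Without Con replicate 1 the medians were 0.48 for the mitochondrial ribosome, 0.44 for OXPHOS and 0.47 for NRF2, and hypoxia was not called (-0.15). Without Con replicate 5 neither OXPHOS (0.06) nor the mitochondrial mRNAs (0.25) was called and NRF2 was 0.17. OXPHOS was not called without Con replicate 4 (0.07) or 14 (-0.01), and its median was 0.24 without Mn replicate 8, 0.08 without Mn replicate 12 and 0.07 without Mn replicate 20. The mitochondrial ribosome was 0.13 without Con replicate 14, hypoxia was not called without Con replicate 12 (-0.15) and was -0.17 without Mn replicate 20, and proliferation was 0.40 without Mn replicate 20. The mitochondrial mRNAs were not called without Mn replicate 3 (0.30), 12 (0.28) or 21 (0.28). Reactive astrocyte genes were not called without Con replicate 5 (0.53), 12 (0.36) or 14 (0.36) or Mn replicate 7 (0.35), 12 (0.41) or 20 (0.33). Heat shock genes were not called without Con replicate 1 (-0.11), 4 (-0.09), 12 (-0.10) or 13 (-0.15) or Mn replicate 7 (-0.10), 8 (-0.18) or 20 (-0.06). Their median was -0.20 without Con replicate 5, -0.21 without Mn replicate 3 and -0.32 without Mn replicate 21.

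The remaining lists missed the threshold over all cells. Their median log2 fold changes and camera adjusted p were -0.16 for cytosolic ribosomal proteins (0.0697), 0.18 for double-stranded RNA and nucleic acid sensing (0.0912), 0.13 for the integrated stress response (0.0912) and -0.26 for cholesterol synthesis (0.0912). They were -0.25 for lysosome and autophagy (0.116), -0.17 for manganese and iron handling (0.144) and -0.12 for immediate early genes (0.144). The values were -0.33 for metallothioneins and zinc export (0.267), -0.14 for p53 and apoptosis (0.267), 0.02 for NF-kB and cytokines (0.354) and 0.05 for mitochondrial RNA metabolism (0.451). They were 0.05 for the unfolded protein response of the endoplasmic reticulum (0.461), 0.21 for astrocyte transport and homeostasis (0.461) and 0.06 for parkinsonism genes (0.594). For the synapse list the median was -0.00 with a mean of 0.06 and a test direction of down (camera adjusted p = 0.830), and for mitochondrial stress and mitophagy it was -0.01 with a mean of 0.02 and a direction of up (0.953).

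With edgeR no gene of 24248 passed over all cells, with 2283 at an unadjusted p under 0.05, and DESeq2 called 117 (79 higher, 38 lower). Adjusted over the list alone, 4 interferon-stimulated genes, 5 sensing genes and 1 mitochondrial RNA metabolism gene were called higher and 1 sensing gene lower. All 9 list calls over all cells were lost with an estimated correlation between genes, where the adjusted p lay between 0.789 and 0.821. The test fry, which tests whether a list's genes move one way without comparing them with other genes, gave no adjusted p under 0.142 in any class with all its libraries.

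**Figure D3:**
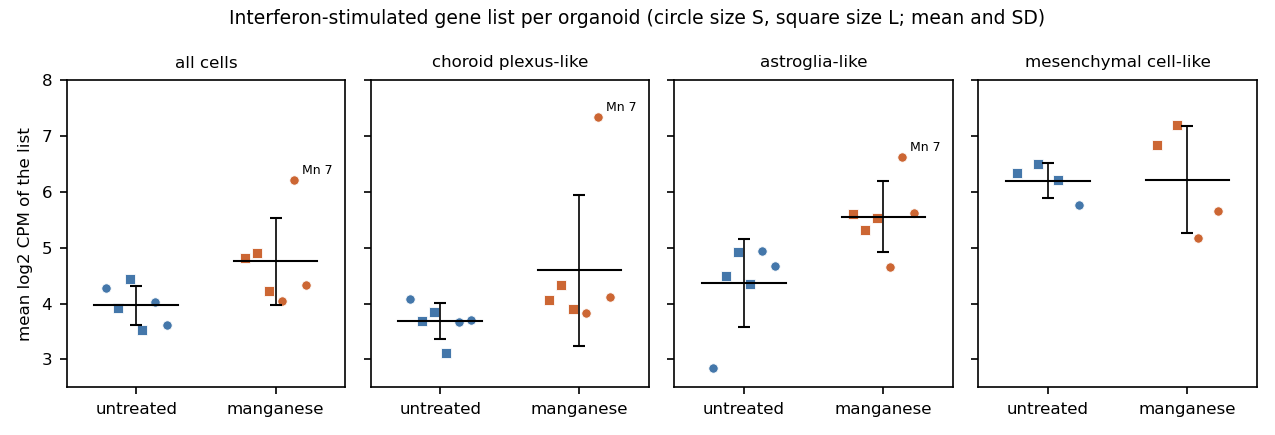
The vertical axis gives the mean log2 CPM of the measured interferon-stimulated genes, with 1 panel for all cells and for each class, untreated organoids on the left and manganese-exposed organoids on the right. Each point is 1 organoid (circle size S, square size L), the line is the mean and the bar is 1 SD. Mn replicate 7 stands at 6.20 over all cells, 7.33 in choroid plexus-like cells and 6.62 in astroglia-like cells.

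In choroid plexus-like cells, genes of hypoxia and glycolysis fell as a list in exposed organoids. Of 41 measured members 28 were lower, with a median log2 fold change of -0.23, and 5 of 6 exposed organoids lay below the untreated mean (camera adjusted p = 0.000214). The adjusted p was 0.789 with an estimated correlation, and the median was -0.15 without Mn replicate 20. The groups filled clusters of this class unevenly: cluster 6 held 4536 untreated and 954 exposed cells, cluster 16 2754 and 383, and cluster 11 692 and 3362. VEGFA, the growth factor for blood vessels, was measured at 551 ± 65.2 CPM in untreated and 357 ± 53.6 CPM in exposed organoids (SD, n = 6 each), and each exposed organoid lay below each untreated one. The glucose transporter SLC2A1 was measured at 291 ± 39.4 and 169 ± 29.9 CPM, the glycolytic enzyme HK2 at 54.9 ± 25.4 and 28.9 ± 11.6 CPM, and NDRG1 at 53.9 ± 33.0 and 17.5 ± 8.29 CPM. Their log2 fold changes were -0.63 ± 0.19, -0.79 ± 0.19, -0.87 ± 0.22 and -1.46 ± 0.26 (SE, edgeR adjusted p = 0.328, 0.289, 0.289 and 0.289), so none passed alone. Cholesterol synthesis genes also fell as a list (19 of 26 lower, 5 of 6 organoids, -0.41, camera adjusted p = 0.000972, or 0.789 with an estimated correlation). SREBF2, the transcription factor that controls them, was measured at 57.0 ± 19.2 and 28.4 ± 6.80 CPM (edgeR adjusted p = 0.289). The manganese and zinc importer SLC39A14 had a log2 fold change of -0.63 ± 0.21 (edgeR adjusted p = 0.335).

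Interferon-stimulated genes rose as a list in choroid plexus-like cells, with 46 of 49 members and 6 of 6 exposed organoids higher and a median of 1.23 (camera adjusted p = 3.19e-10). The adjusted p was 0.789 with an estimated correlation, and the median was 0.21 without Mn replicate 7. The mitochondrial ribosome rose as a list, with 48 of 51 members and 6 of 6 organoids higher (0.35, camera adjusted p = 1.95e-08). So did the mitochondrially encoded mRNAs, with 13 of 13 members and 6 of 6 organoids higher (0.50, camera adjusted p = 0.000206). Both had an adjusted p of 0.789 with an estimated correlation. TRMT10C was measured at 24.8 ± 5.24 and 39.2 ± 10.2 CPM, and the mitochondrial ribosome subunit MRPS31 at 22.8 ± 2.77 and 35.7 ± 6.93 CPM, each higher in 6 of 6 (edgeR adjusted p = 0.289 and 0.293). HSD17B10, a partner of TRMT10C in the same complex, had a log2 fold change of 0.93 ± 0.34 (edgeR adjusted p = 0.347). OXPHOS genes (65 of 73 members, 4 of 6 organoids, 0.18, camera adjusted p = 0.00157), NRF2 genes (25 of 32, 6 of 6 organoids, 0.19, 0.0043) and the unfolded protein response (24 of 28, 6 of 6 organoids, 0.21, 0.0164) rose as lists too. Their adjusted p was 0.821, 0.789 and 0.821 with an estimated correlation. Genes of at most 10000 bp had a median of 0.178 in these cells and genes of at least 100000 bp -0.242. Among NRF2 targets, the detoxifying enzyme AKR1C1 had a log2 fold change of 2.37 ± 0.55 and the antioxidant enzyme SRXN1 1.06 ± 0.34 (edgeR adjusted p = 0.289 and 0.328). The serine synthesis enzymes PHGDH and PSAT1 had 0.79 ± 0.23 and 0.88 ± 0.28 (edgeR adjusted p = 0.325 and 0.328). With edgeR no gene of 21772 passed, with 2663 at an unadjusted p under 0.05, and DESeq2 called 206 (91 higher, 115 lower). With the ribosomal protein level of each library as a covariate, chosen after the data were seen, edgeR called 1051 (398 higher, 653 lower), NDRG1, SLC2A1 and VEGFA among the lower ones. Adjusted over the list alone, 8 hypoxia genes, 1 cholesterol gene and 1 sensing gene were lower, 1 NRF2, 1 sensing and 1 mitochondrial RNA metabolism gene were higher, and no interferon-stimulated gene was called. All 8 list calls were lost with an estimated correlation (adjusted p between 0.789 and 0.821). Without Con replicate 1 the medians were 0.60 for the mitochondrial ribosome, 0.42 for OXPHOS and 0.40 for NRF2, and without Con replicate 14 the ribosome was 0.21. OXPHOS was not called without Con replicate 5 (0.09), Con replicate 14 (0.05) or Mn replicate 7 (0.08). Its median was 0.28 without Con replicate 13, 0.10 without Con replicate 4, 0.29 without Mn replicate 8, 0.30 without Mn replicate 21, 0.12 without Mn replicate 12 and 0.10 without Mn replicate 20. The unfolded protein response was not called without Con replicate 5 (0.11), Con replicate 14 (0.13), Mn replicate 3 (0.13) or Mn replicate 21 (0.12) and was 0.32 without Con replicate 12, and NRF2 was not called without Con replicate 5 (0.12).

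**Figure D4:**
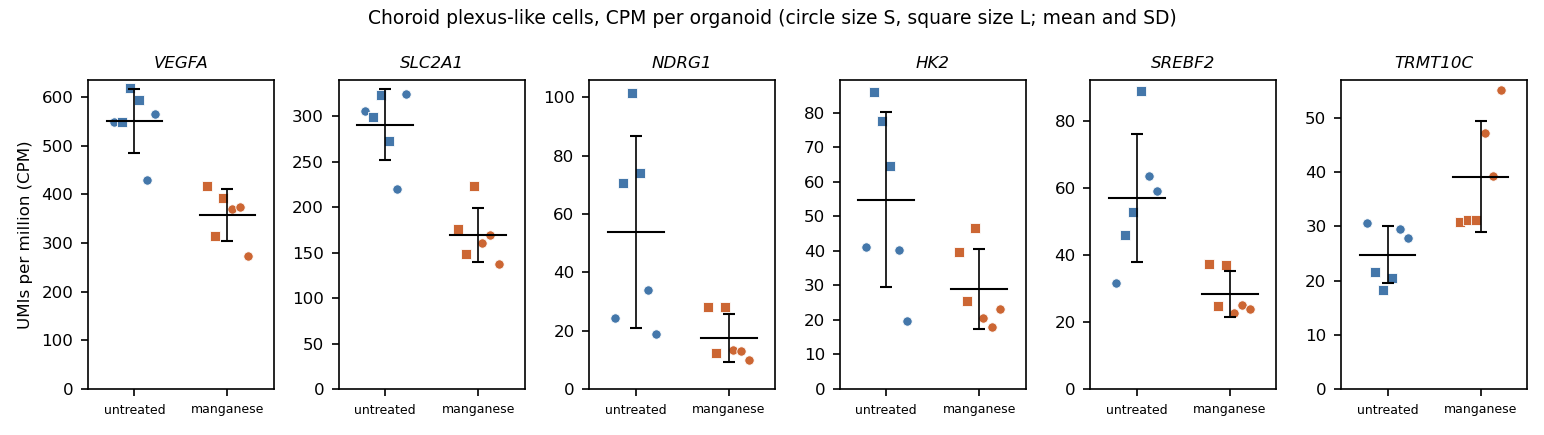
The vertical axis of each panel gives CPM of 1 gene in choroid plexus-like cells, untreated organoids on the left and manganese-exposed organoids on the right. Each point is 1 organoid (circle size S, square size L), the line is the mean and the bar is 1 SD. SLC2A1 lies between 220 and 325 CPM in untreated and between 138 and 224 CPM in exposed organoids.

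In astroglia-like cells, nuclear genes of the respiratory chain rose as a list in exposed organoids by camera, whose calls random splits gave in like number. Of 73 measured OXPHOS genes 71 were higher, with a median log2 fold change of 0.79 in 6 of 6 organoids (camera adjusted p = 4.32e-22, or 0.789 with an estimated correlation). The groups filled different clusters of this class: cluster 3 held 2 untreated and 7321 exposed cells, cluster 4 6797 and 6, cluster 21 2178 and 67, and cluster 22 174 and 1908. Clusters 21 and 22, led by MYOC, SPARCL1 and PENK and by FABP4, APOE and RIPPLY1, are the 2 without GFAP and AQP4. Cluster 21 held 969 of the 1066 astroglia-like cells of Con replicate 5 and 783 of the 838 of Con replicate 14, and cluster 22 held 1803 of the 1965 of Mn replicate 7. Genes of at most 10000 bp had a median of 0.272 in these cells and genes of at least 100000 bp -0.330. The mitochondrial ribosome was higher in 50 of 51 members and 6 of 6 exposed organoids (0.62, camera adjusted p = 7.38e-13, or 0.789 with an estimated correlation). NDUFB2, a complex I subunit, was measured at 137 ± 44.1 CPM in untreated and 315 ± 112 CPM in exposed organoids, and the ribosome subunit MRPS15 at 25.9 ± 8.84 and 64.1 ± 11.2 CPM (SD, n = 6 each). The mitochondrially encoded mRNAs rose as a list, with 11 of 13 members and 6 of 6 organoids higher (0.67, camera adjusted p = 0.00305, or 0.789 with an estimated correlation). Among them were MT-ND1 transcripts at 229 ± 28.1 and 387 ± 72.7 CPM (edgeR adjusted p = 0.103). Their median was 0.44 without Con replicate 1 and 0.38 without Mn replicate 7. Interferon-stimulated genes rose as a list, with 45 of 49 members and 6 of 6 organoids higher (0.97, camera adjusted p = 5.51e-12, or 0.789 with an estimated correlation). Their median was 0.63 without Mn replicate 7. The immunoproteasome subunit PSMB8 was measured at 31.5 ± 9.56 and 103 ± 35.1 CPM and the DNA sensor IFI16 at 19.7 ± 7.58 and 127 ± 98.0 CPM. IRF9, a subunit of the interferon-activated transcription factor, was measured at 27.4 and 75.2 CPM. All 3 were higher in 6 of 6 exposed organoids. Their log2 fold changes were 1.74 ± 0.30, 2.63 ± 0.52 and 1.44 ± 0.32 (SE, edgeR adjusted p = 0.0954 for each), so none passed alone.

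Cholesterol synthesis genes rose in astroglia-like cells (21 of 26 members, 6 of 6 organoids, 0.67, camera adjusted p = 0.0001, or 0.789 with an estimated correlation), with FDPS, an enzyme of the mevalonate pathway, at 40.2 ± 13.5 and 107 ± 44.5 CPM. NRF2 genes rose (28 of 30, 6 of 6 organoids, 0.67, camera adjusted p = 1.12e-07, or 0.789 with an estimated correlation). Reactive astrocyte genes rose as well (19 of 25, 5 of 6 organoids, 0.74, camera adjusted p = 0.000511, or 0.789 with an estimated correlation), with TIMP1, an inhibitor of matrix proteases, at 274 ± 106 and 785 ± 264 CPM (edgeR adjusted p = 0.0954). NF-kB and cytokine genes (23 of 29, 5 of 6 organoids, 0.98, camera adjusted p = 0.00167) and proliferation genes (17 of 22, 5 of 6 organoids, 0.70, 0.00327) rose as lists, with an adjusted p of 0.814 and 0.789 with an estimated correlation. Cytosolic ribosomal proteins (66 of 72, 4 of 6 organoids, 0.23, camera adjusted p = 0.0085) and lysosome genes (22 of 30, 6 of 6 organoids, 0.15, 0.035) did too, with an adjusted p of 0.821 and 0.789 with an estimated correlation. Immediate early genes fell (15 of 23 lower, 4 of 6 organoids, -0.39, camera adjusted p = 0.0429, or 0.821 with an estimated correlation). The activity-induced factor EGR1 was measured at 129 ± 48.4 and 50.0 ± 14.4 CPM, lower in 6 of 6 (-1.39 ± 0.28, edgeR adjusted p = 0.0954). The p53 and apoptosis list fell by the fit (19 of 29 lower, -0.32, camera adjusted p = 0.0226, or 0.789 with an estimated correlation), although its mean level lay below the untreated mean in only 1 of 6 exposed organoids. With edgeR no gene of 17249 passed, with 3499 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0954, and DESeq2 called 1576 (863 higher, 713 lower). Adjusted over the list alone, 45 OXPHOS, 17 interferon-stimulated, 15 mitochondrial ribosome, 8 cholesterol, 7 NRF2, 7 proliferation, 6 reactive astrocyte and 3 mitochondrial RNA metabolism genes were higher. So was 1 gene each of the mitochondrially encoded, p53, sensing, metallothionein and parkinsonism lists, and 4 p53 genes, 1 immediate early gene and 1 reactive astrocyte gene were lower. All 13 list calls were lost with an estimated correlation (adjusted p between 0.789 and 0.821). Con replicate 1 held only 28 of these cells. With libraries of at least 100 cells (5 in each group, a minimum chosen after the data were seen) edgeR called 0 of 19102 genes, with 4291 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0728. In those libraries fry, adjusted over the lists of this class alone, gave 0.0295 for interferon-stimulated and p53 genes and 0.0417 for OXPHOS, mitochondrial ribosome and NRF2 genes. Camera with an estimated correlation called 0 lists there, with an adjusted p of 0.175 for interferon-stimulated and p53 genes and 0.293 for the others named. With clustering at resolution 0.5 this class held 118 cells of Mn replicate 7 in place of 1965 and 55 of Con replicate 5 in place of 1066, and edgeR called 0 of 12191 genes, with 1584 at an unadjusted p under 0.05. Proliferation was 0.41 without Mn replicate 20, and the cytokine list was not called without Mn replicate 21 (0.32). The p53 list was not called without Con replicate 4 (-0.32), 12 (-0.38) or 13 (-0.27) or Mn replicate 7 (-0.41), and cytosolic ribosomal proteins were not called without Con replicate 4 (0.12), 5 (0.16) or 14 (0.14) or Mn replicate 7 (0.09). Immediate early genes were not called without Con replicate 1 (-0.50), 4 (-0.12), 12 (-0.40) or 13 (-0.37) or Mn replicate 7 (-0.27), 8 (-0.29) or 20 (-0.35), and were -0.78 without Mn replicate 21. Lysosome genes were not called without Con replicate 5 (0.20), 13 (0.18) or 14 (0.22) or Mn replicate 3 (0.15), 12 (0.19) or 21 (0.13). Their median was 0.10 without Con replicate 1, 0.36 without Con replicate 12, 0.25 without Con replicate 4 and 0.23 without Mn replicate 8.

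In mesenchymal cell-like cells, counted in 4 untreated and 4 exposed organoids with 22 to 206 cells each, OXPHOS genes rose as a list. Of 73 members 67 were higher, with a median log2 fold change of 0.76 (camera adjusted p = 5.51e-12, or 0.789 with an estimated correlation), although the list's mean level was above the untreated mean in 2 of 4 exposed organoids. The mitochondrial ribosome (41 of 48, 3 of 4 organoids, 0.56, camera adjusted p = 0.000206) and cytosolic ribosomal proteins (59 of 72, 3 of 4 organoids, 0.42, 0.000511) rose as well, with an adjusted p of 0.789 and 0.821 with an estimated correlation. NRF2 genes (20 of 24, 3 of 4 organoids, 0.65, camera adjusted p = 0.000985) and the mitochondrially encoded mRNAs (11 of 12, 2 of 4 organoids, 0.69, 0.00178) did too, and both had an adjusted p of 0.789 with an estimated correlation. Hypoxia genes (31 of 37 lower, 3 of 4 organoids, -0.37, camera adjusted p = 0.0036) and heat shock genes (16 of 22 lower, 2 of 4 organoids, -0.33, 0.0122) fell, and both had an adjusted p of 0.789 with an estimated correlation. Genes of at most 10000 bp had a median of 0.386 in these cells and genes of at least 100000 bp -0.215. The inducible chaperone HSPA1A was measured at 182 ± 126 and 35.1 ± 24.4 CPM (SD, n = 4 each) and PSAT1 at 11.4 and 61.9 CPM (edgeR adjusted p = 0.645 for both). With edgeR no gene of 6913 passed, with 514 at an unadjusted p under 0.05, and DESeq2 called 2, both higher. All 7 list calls were lost with an estimated correlation (adjusted p between 0.789 and 0.821). The mitochondrial mRNAs were not called without Mn replicate 20 (0.38), hypoxia was not called without Con replicate 13 (-0.27) and was -0.58 without Con replicate 4 and -0.57 without Mn replicate 8, and the mitochondrial ribosome was 0.28 without Con replicate 14. Heat shock genes were not called without Con replicate 4 (-0.40), 12 (-0.28) or 13 (-0.32), and cytosolic ribosomal proteins were not called without Con replicate 4 (0.29), Con replicate 14 (0.29) or Mn replicate 8 (0.15).

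Whether a list answered manganese differently in choroid plexus-like and astroglia-like cells was tested on the difference itself. Cholesterol synthesis genes came closest: the choroid plexus minus astroglia level (mean log2 CPM) was 0.75 ± 0.65 in untreated and -0.26 ± 0.42 in exposed organoids (SD, n = 6 each), a difference of -1.01. The two-sided exact permutation test gave p = 0.00216, the smallest it can give, and adjusted p = 0.0541 over 25 lists, which missed the threshold, and every other list had an adjusted p of at least 0.471. Con replicate 1, with 28 astroglia-like cells, lay lowest of the untreated organoids for the cholesterol list in that class (3.06 mean log2 CPM, next 4.26). The groups also filled different astroglia-like clusters.

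The size label was compared within the same fits. In mesenchymal cell-like cells 47 genes differed between size L and size S organoids (11 higher and 36 lower in L, edgeR), with 1184 at an unadjusted p under 0.05 and 186 called by DESeq2. PTGDS, a prostaglandin synthase (log2 fold change 5.97), and the chemokine CCL2 (3.35) were higher in L, and the glycolytic regulators PFKFB3 (-4.06) and PFKFB4 (-3.79) were lower in L, all chosen after their values were seen. In all cells, astroglia-like cells and choroid plexus-like cells edgeR called 0 genes by size, with 1423, 851 and 1826 at an unadjusted p under 0.05, and DESeq2 called 45, 1 and 68. In mesenchymal cell-like cells the interaction of treatment and size was called for 1 gene, ACTR1A, a subunit of the dynein activator complex (log2 difference 7.94, edgeR adjusted p = 0.0488). Untreated size S organoids are there represented by Con replicate 4 alone (29 cells), which the fit assumes to vary like the other libraries. The interaction gave 0 genes by edgeR in all cells, astroglia-like and choroid plexus-like cells, with 502, 953 and 349 at an unadjusted p under 0.05, and DESeq2 called 6, 33, 0 and 25 in these and in mesenchymal cell-like cells.

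In the clusters led by TPH1 and RCVRN, the stress-induced transcription factors ATF3 and DDIT3 rose in exposed organoids. ATF3 went from 31.4 ± 10.2 to 96.1 ± 20.97 CPM (log2 fold change 1.83 ± 0.36, edgeR adjusted p = 0.00739), with 5 untreated and 4 exposed organoids. DDIT3 went from 188 ± 84.6 to 573 ± 225 CPM (1.59 ± 0.39, edgeR adjusted p = 0.0263). PSAT1 rose from 18.6 ± 4.72 to 65.4 ± 28.3 CPM (edgeR adjusted p = 0.00763) and HERPUD1, which acts in the degradation of misfolded proteins, from 152 ± 86.8 to 431 ± 165 CPM (0.0317). The glutamate receptor subunits GRIA1 and GRIA2 fell, from 43.6 ± 21.1 to 8.86 ± 7.20 CPM and from 106 ± 50.3 to 39.4 ± 9.31 CPM (edgeR adjusted p = 0.0245 and 0.0311). ISG15 rose (2.20 ± 0.51, edgeR adjusted p = 0.0206) and was higher in 3 of 4 exposed organoids, while the other genes named above moved the same way in 4 of 4. No correction for free RNA was made, and in Mn replicate 7 ISG15 was counted in 13.4% of the 5576 cells without a name, 4578 of which lay in these clusters, against 69.7% of its choroid plexus-like cells. KCNK3, a potassium channel, fell (-6.16 ± 1.06, edgeR adjusted p = 0.00297), though its untreated mean of 495 ± 1072 CPM came mostly from Con replicate 1, without which it was not called (-1.11, adjusted p = 0.120). In all, edgeR called 242 genes of 13691 (41 higher, 201 lower), with 2596 at an unadjusted p under 0.05, and DESeq2 called 555. With the cytosolic ribosomal protein level as a covariate edgeR called 6, with doublets kept 56, and within clusters 7, 13, 18 and 19 taken alone 0, 0, 33 and 2. The edgeR count was 32 without Mn replicate 7, 72 without Con replicate 4, 140 without Mn replicate 12, 161 without Con replicate 14 and 686 without Con replicate 1. Without Con replicate 4 none of DDIT3 (1.16), ATF3 (1.58), PSAT1 (1.74), HERPUD1 (1.09), GRIA1 (-1.12) and GRIA2 (-1.27) was called, with edgeR adjusted p from 0.120 to 0.529. Without Mn replicate 7 DDIT3 (1.46), PSAT1 (1.74), HERPUD1 (1.505), ISG15 (1.69), GRIA1 (-1.82) and GRIA2 (-1.32) were not called. The same held without Con replicate 5 for DDIT3 (1.61), HERPUD1 (1.51), ISG15 (1.69) and GRIA2 (-1.44), without Mn replicate 3 for HERPUD1 (1.39) and GRIA2 (-1.33), and without Mn replicate 12 for GRIA1 (-1.84) and GRIA2 (-1.40).

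As lists in these clusters, OXPHOS genes rose (72 of 73 members, 4 of 4 organoids, 0.65, camera adjusted p = 9.35e-21, or 0.410 with an estimated correlation). Genes of at most 10000 bp had a median of 0.527 in these clusters and genes of at least 100000 bp -0.677. The mitochondrial ribosome (47 of 51, 0.73, camera adjusted p = 6.72e-12) and cytosolic ribosomal proteins (71 of 72, 0.44, 2.11e-09) rose with 3 of 4 organoids each, and their adjusted p was 0.410 and 0.4929 with an estimated correlation. The unfolded protein response had 25 of 27 members higher, 3 called and 7 adjusted over the list alone (0.70, camera adjusted p = 2.85e-09, or 0.390 with an estimated correlation). The integrated stress response had 32 of 39 higher, 6 called and 13 adjusted over the list alone (0.64, camera adjusted p = 7.18e-08, or 0.410 with an estimated correlation). Each was higher in 3 of 4 exposed organoids. Synapse genes fell, with 29 of 33 members lower, 2 called and 11 adjusted over the list alone (-0.82, 3 of 4 organoids, camera adjusted p = 3.7e-05), and interferon-stimulated genes rose, with 29 of 33 higher, 3 called higher and 1 lower (0.77, 6.79e-05). Both had an adjusted p of 0.410 with an estimated correlation. The mitochondrially encoded mRNAs rose as a list (12 of 13, 3 of 4 organoids, 0.50, camera adjusted p = 0.00253), while their share of UMIs was 0.872 ± 0.370% and 1.22 ± 0.338% (exact permutation p = 0.198). The adjusted p of that list was 0.4929 with an estimated correlation. The lists of NRF2 (23 of 29, 0.25, camera adjusted p = 0.000498), reactive astrocyte (12 of 16, 0.40, 0.00288), immediate early (14 of 16, 0.50, 0.00685) and lysosome genes (21 of 28, 0.29, 0.0132) rose too. So did those of p53 (17 of 26, 0.35, camera adjusted p = 0.0199), mitochondrial stress (22 of 31, 0.18, 0.0199) and mitochondrial RNA metabolism genes (20 of 32, 0.15, 0.0454). Each of these 7 was higher in 3 of 4 exposed organoids, and their adjusted p lay between 0.390 and 0.4929 with an estimated correlation. The p53 and immediate early lists fell in astroglia-like cells (adjusted p = 0.789 and 0.821 with an estimated correlation), and whether they differ between the classes was not tested. The 4 clusters were filled unevenly by the groups: clusters 7 and 19 held 5265 and 2446 untreated but 210 and 66 exposed cells, and clusters 13 and 18 held 204 and 736 untreated but 3560 and 2243 exposed cells.

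**Figure D5:**
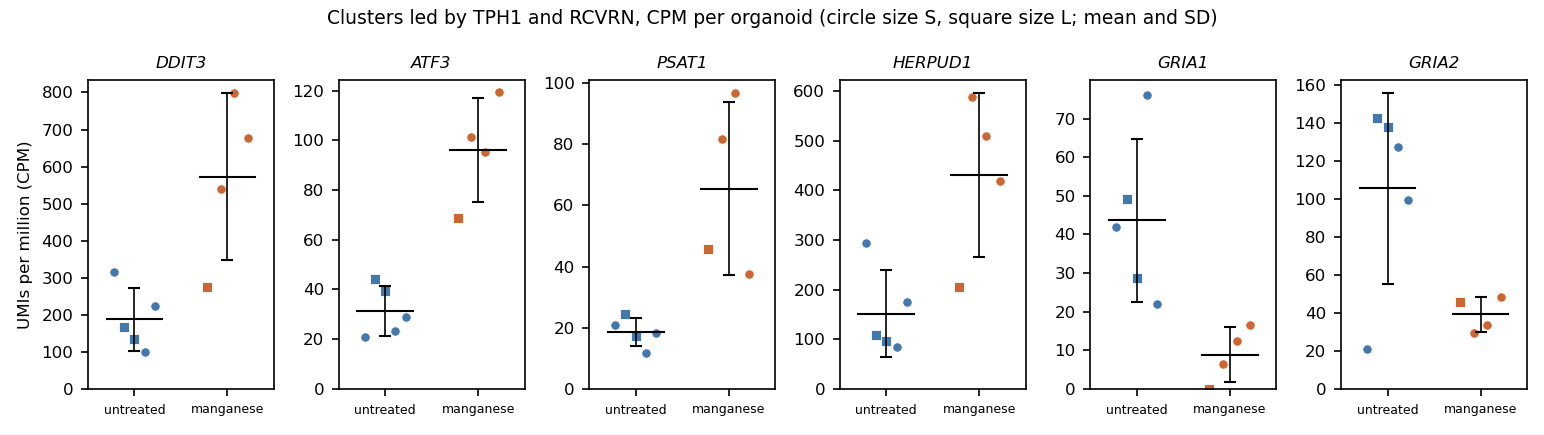
The vertical axis of each panel gives CPM of 1 gene in the clusters led by TPH1 and RCVRN, untreated organoids on the left and manganese-exposed organoids on the right. Each point is 1 organoid (circle size S, square size L), the line is the mean and the bar is 1 SD. ATF3 lies between 20.97 and 44.3 CPM in untreated and between 68.7 and 119 CPM in exposed organoids.

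On the genome build GRCh38, TRMT10C (ENSG00000174173) lies on chromosome 3 from 101561862 to 101566446, NDRG1 (ENSG00000104419) on chromosome 8 from 133237171 to 133302022, VEGFA (ENSG00000112715) on chromosome 6 from 43770184 to 43786487 and SLC2A1 (ENSG00000117394) on chromosome 1 from 42925375 to 42959176. ISG15 (ENSG00000187608) lies on chromosome 1 from 1001138 to 1014540, and PSMB8 (ENSG00000204264) on chromosome 6 from 32840717 to 32844703. ATF3 (ENSG00000162772) lies on chromosome 1 from 212565334 to 212620777, DDIT3 (ENSG00000175197) on chromosome 12 from 57516588 to 57521737 and GRIA1 (ENSG00000155511) on chromosome 5 from 153489615 to 153813869.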

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

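Of the tests in this part, those on damaged cells, ribosomal protein sets, microglia markers, a general interferon response, the clusters filled by each group and the ribosomal covariate in the TPH1 and RCVRN clusters, long genes in the ribosomal protein sets, and the random splits for the treatment effect, for the lists and at an unadjusted p, were chosen only after the result was seen. Values were compared within 196 groups of 4 to 6 organoids, and in 26 of them 1 organoid lay far from the others by Dixon's ratio. Chance alone gives about 1 such group in 20. Of the 26, 7 were in Mn replicate 7, and more were in Con replicate 1.

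Mn replicate 7 stood far above the other exposed organoids in interferon-stimulated genes. Over all cells it held 123 CPM of IFIT3 (next highest 16.5), 120 of IFIT2 (18.9), 445 of ISG15 (38.1) and 92.1 of MX1 (13.7). In choroid plexus-like cells it held 283 CPM of IFIT2 (26.6) and 1057 of ISG15 (34.6), and a mean log2 CPM of 7.33 over the list (4.32). ISG15 was counted in 69.7% of its 854 choroid plexus-like cells (median 12778 UMIs) and 57.7% of its 1965 astroglia-like cells (10006 UMIs), against 9.37 to 13.6% in untreated choroid plexus-like cells and 13.8 to 24.0% in untreated astroglia-like cells (1567.5 to 12948 UMIs). Mn replicate 8 came next, with 26.7 and 27.7%. ISG15 was counted in 13.4% of the cells of Mn replicate 7 in clusters with no name (3730 UMIs), mostly the TPH1 and RCVRN clusters, where expression and free RNA were not separated, and in 1.92 to 3.03% of excitatory neuron-like cells of Mn replicates 8, 12 and 20 (1614.5 to 2784.5 UMIs). Of 13 IFNB1 transcripts in all libraries 10 were in this organoid, as were 743 of 1442 of CXCL11 (424 in Con replicate 5), 1 of 7 of IFNL1 and 0 of 1 of IFNG.

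Technical and biological readings of this organoid were set against each other. Immune cells are argued against: 0 of the 7 microglia or macrophage markers had their highest level there, and the most abundant of them, PTPRC, was at 15.99 CPM against 23.2 in Mn replicate 3. Free RNA from choroid plexus-like cells is argued against as well, since the astroglia to choroid plexus ratio was 0.569 for ISG15 but 0.00353 for TTR. A response shared by the exposed organoids cannot be the whole account in choroid plexus-like cells, where the list median was 0.21 without this organoid and 1.23 with it. In astroglia-like cells most of it stayed (0.634 and 0.971), which fits a shared response, but the groups filled different clusters of this class. ISG15 was counted there in 13.7 to 21.6% of cells in Mn replicates 3, 12, 20 and 21, against 13.8 to 24.0% in untreated organoids. Con replicate 1, with 28 of these cells, also lay lowest of the untreated organoids for the list (2.84 mean log2 CPM, next 4.35). Over all cells (0.425 and 0.817) the values leave a shared response open. By camera with the preset correlation the list was still called without this organoid in all 3. That call decides little, since with all libraries no list was called with an estimated correlation. With all libraries 14 of 40 random splits also gave as small a camera p for this list in choroid plexus-like cells. An interferon response that is stronger in 1 organoid may be biological, as a hypothesis, and whether manganese or another feature of that organoid set it off was not tested.

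The mitochondrially encoded share of UMIs was 0.367 percentage points higher in exposed organoids, and higher in 22 of the 23 clusters that both groups filled. Over all cells a different mix of clusters and damaged cells are argued against. The mix predicted a difference of -0.0974, in the other direction, and the difference was 0.335 with cells above 10% left out. Taking the ribosomal protein sets apart did not remove the difference, since the smaller of the differences within a set was 0.364. The groups were not matched on the level within the sets, so this does not settle the level itself. Above the median it was 11.42 to 11.46 mean log2 CPM in untreated and 10.83 to 11.18 in exposed organoids. Below the median it was 10.09 to 10.28 and 10.15 to 10.71. In choroid plexus-like cells the difference was 1.25 above the median ribosomal level but 0.0617 below it, so the sets stay open there. Fewer UMIs from long genes are argued against in the libraries above the median ribosomal level, where long genes took 1.54 percentage points more in exposed organoids and the log2 share still differed by 0.334. They stay open in the other libraries, where long genes took -6.97 points, and over all 12, where the log2 ratio of mitochondrially encoded to short-gene UMIs differed by 0.228 (exact permutation p = 0.190) and the log2 share by 0.319 (p = 0.0108, the same test). A response to manganese may contribute, as an untested hypothesis beside the explanations left open.

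In the clusters led by TPH1 and RCVRN, 242 genes were called. Of 40 random splits only the real one gave as many, the lowest share that 40 splits can give, and the highest other gave 62. With 1 of 40 splits as large, chance is argued against for that count taken alone. It is not excluded over all the results counted by splits, since this class was defined after the data were seen. The count was 56 with doublets kept and 32 without Mn replicate 7, below that highest other, and no such splits were drawn there. With libraries of at least 100 cells the genes that fell had a median of -1.95 as before. They were chosen for falling in libraries that include these, so that median cannot decide about few cells per library. In the 4 untreated and 3 exposed organoids left, edgeR called 338 genes (60 higher, 278 lower), so a count of this size did not need the smaller libraries. Different clusters filled by each group fit the genes that fell, whose median was -1.95 over all 4 clusters and -0.839 within cluster 7 (176 of 201 genes measured), -0.678 within cluster 19 (148), -0.538 within cluster 18 (36) and -0.537 within cluster 13 (19). They stay open for the genes that rose, at 1.73 over all 4 and 0.966 (36 of 41), 1.20 (28), 1.27 (22) and 0.879 (17) in the same order. Clusters 7 and 19 held 2 exposed organoids each, and the genes measured differ between clusters. Long genes fit too: the genes that fell had a median span 43.8 times that of the genes that rose (334639 and 7632 bp), as a lower share of nuclear RNA would give. The ribosomal protein level stays open. With it as a covariate the call ended at 6 genes, 0 of them lower, and the median of the fallen genes moved from -1.95 to -1.31. Of the fallen genes 199 of 201 had the same direction as before, which decides little, since they were chosen in the same libraries. Part of this response may therefore be a shift of cell states or RNA content between organoids.

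The other values that stood apart are given without explanation. VEGFA in choroid plexus-like cells was 430 CPM in Con replicate 4, below the other untreated organoids (549 and higher). PHGDH in these cells was 17.6 CPM in Con replicate 1 (next 10.3), and the cholesterol synthesis list was at 5.25 mean log2 CPM in Mn replicate 12 (next 4.72). In astroglia-like cells IRF9 was 19.2 CPM in Con replicate 14, TIMP1 was 344 CPM in Mn replicate 3 and FDPS was 14.7 CPM in Con replicate 1. Con replicate 1, with 28 astroglia-like cells, also lay lowest for 7 lists there: mitochondrially encoded mRNAs (7.17 mean log2 CPM), interferon-stimulated genes (2.84), NRF2 (3.89), p53 (2.84), cholesterol synthesis (3.06), lysosome (3.69) and proliferation (0.31). In the TPH1 and RCVRN clusters Con replicate 1 held 20.97 CPM of GRIA2 (next 99.4) and 2412 CPM of KCNK3 (next 20.98). Con replicate 13 held the highest untreated share of astroglia-like (57.4%), Cajal-Retzius cell-like (2.58%) and excitatory neuron-like cells (0.227%), and Con replicate 14 that of mesenchymal cell-like cells (2.15%). The manganese effect on ACTR1A differed between size L and size S by 7.94 on the log2 scale in mesenchymal cell-like cells, by the test of the interaction. That value rests on Con replicate 4 (29 cells) as the lone untreated size S library, and chance cannot be excluded for it (10 of 30 random splits).

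Random splits of the organoids were also counted for the other edgeR results. Where no gene was called every split gives as many, so those counts decide nothing: for manganese in all cells (40 of 40 splits, real count 0, highest other 1), astroglia-like (40 of 40, 0, 328), choroid plexus-like (40 of 40, 0, 2651) and mesenchymal cell-like cells (35 of 35, 0, 7), for the size label in all cells (40 of 40, 0, 0), astroglia-like (40 of 40, 0, 493) and choroid plexus-like cells (40 of 40, 0, 4), and for the interaction in the same 3 sets (40 of 40, 0, with 0, 473 and 0). The split with 2651 genes set Con replicates 1 and 13 and Mn replicates 3, 7, 12 and 20 against the rest, which points to a structure of the samples. Genes at an unadjusted p under 0.05 were therefore counted in the same splits. For manganese in astroglia-like cells the real split alone gave as many (1 of 40, 3499, highest other 2926), so chance is argued against for that count taken alone. It is not excluded over the 10 results counted in this way after the data were seen. The count was 1584 with Leiden resolution 0.5 (12191 genes tested) and 2531 with the ribosomal covariate, where no such splits were drawn. Chance cannot be excluded for manganese in all cells (10 of 40, 2283, 5460), choroid plexus-like (6 of 40, 2663, 7266) and mesenchymal cell-like cells (7 of 35, 514, 1088). Nor can it for the size label in all cells (11 of 40, 1423, 4786), astroglia-like (13 of 40, 851, 3346) and choroid plexus-like cells (6 of 40, 1826, 6013), or for the interaction in these sets (24 of 40, 502, 4661, then 13 of 40, 953, 2591, then 33 of 40, 349, 3472).

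Of the results with called genes, chance cannot be excluded for the size label (2 of 40 splits, 47, highest other 55) and the interaction (10 of 30, 1, 162) in mesenchymal cell-like cells, or for DESeq2 in choroid plexus-like cells (2 of 40, 206, 4840). Nor can it for the number of lists called by camera in all cells, astroglia-like and choroid plexus-like cells (24 of 40, 31, 44), where adjusting over these 75 tests alone gave 31 calls in place of 30. The median over the other splits was 32 lists. For the interferon list in choroid plexus-like cells 14 of 40 splits gave as small a camera p, so chance cannot be excluded. With the ribosomal covariate, chosen after the data were seen, the real split alone gave as many genes in choroid plexus-like cells (1 of 40, 1051, 2). Chance is argued against there for that count taken alone, but is not excluded over all the models and results counted by splits. It cannot be excluded with the covariate in the TPH1 and RCVRN clusters (25 of 40, 6, 73).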

How the results depend on the processing

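No paired analysis was possible because the groups share only 1 number. The planned clustering without genes called in the all-cell test was not run, since no gene was called, and clustering without genes at an unadjusted p under 0.05 was added after the data were seen. Every alternative for the TPH1 and RCVRN clusters, and those with the ribosomal covariate or the ribosomal sets, was also chosen after seeing the data. Over 1121 comparisons of 49 named genes with their alternatives, 1049 kept direction and side of the threshold, 37 became weaker, 35 stronger and 0 reversed. Outside the TPH1 and RCVRN clusters no gene had passed for manganese, so keeping its side there meant staying not called. Within those clusters 6 named calls were lost without Con replicate 4 and 6 without Mn replicate 7. Of 592 comparisons of the 37 called lists, 447 kept both, 143 became weaker and 2 reversed. Of 140 comparisons of 7 class shares, 125 held, 1 moved and 14 reversed. The edgeR counts of 0 for manganese in all cells and astroglia-like cells also stayed at 0 with RLE factors, no filter, no size covariate, other cell filters and each organoid left out. In each case below the cause was not tested unless said.

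With DESeq2 the manganese effect gave 117 genes in all cells, 1576 in astroglia-like, 206 in choroid plexus-like and 2 in mesenchymal cell-like cells and 555 in the TPH1 and RCVRN clusters, where edgeR gave 0, 0, 0, 0 and 242. It gave 45, 1, 68 and 186 genes by size label in the first 4 of these sets, and 6, 33, 0 and 25 for the interaction. Without the filter on low counts edgeR gave 114 genes for manganese, 798 by size and 125 for the interaction in mesenchymal cell-like cells, 4 for the interaction in astroglia-like cells and 499 in the TPH1 and RCVRN clusters, with more genes tested. Those clusters gave 581 without the size covariate, 56 with doublets kept and 6 with the ribosomal covariate, which gave 1051 in choroid plexus-like cells. Leaving out 1 organoid gave 0 to 1 genes in choroid plexus-like cells (1 without Con replicate 5), 0 to 1 in mesenchymal cell-like cells (1 without Con replicate 4 or Mn replicate 8), and 32 (Mn replicate 7) to 686 (Con replicate 1) in the TPH1 and RCVRN clusters, with 72 without Con replicate 4, 140 without Mn replicate 12 and 161 without Con replicate 14.

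Of 37 list calls, 0 held with an estimated correlation and 0 with fry over all libraries, and 34 to 43 lists were called with 1 organoid left out. With the ribosomal covariate the cytosolic ribosomal protein list turned to down by camera, with medians of 0.00777 in astroglia-like cells (adjusted p = 0.917; 0.09 to 0.34 with 1 organoid left out) and 0.0460 in mesenchymal cell-like cells (0.967; 0.15 to 0.57), which follows from correcting for the list itself. No difference of a list between classes passed under any alternative.

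The all-cell mitochondrially encoded share missed the threshold by the exact permutation test with no mitochondrial limit (0.371, adjusted p = 0.0693), with the median over cells (0.364, 0.0779) and permuted within the ribosomal sets (0.367, 0.060), and ran from 0.316 (without Mn replicate 8) to 0.416 (without Con replicate 4). In choroid plexus-like cells it was 1.25 in the libraries above the median ribosomal level and 0.0617 in those below, and 0.458 (without Mn replicate 20) to 0.797 (without Mn replicate 21). In mesenchymal cell-like cells it ran from -0.134 (without Mn replicate 20) to 0.514 (without Mn replicate 8). The Cajal-Retzius cell-like share reversed to 0.122 with the resolution halved, to 0.795 in log odds and to 0.122 in the added clustering, and ran from -0.274 (without Mn replicate 12) to 0.339 (without Con replicate 13). With 1 organoid left out the difference in share ran from -1.94 (Mn replicate 20) to 15.02 (Con replicate 13) for astroglia-like, from -15.8 (Con replicate 5) to 2.83 (Mn replicate 20) for choroid plexus-like cells and from -11.9 (Mn replicate 7) to 3.55 (Con replicate 5) for the TPH1 and RCVRN clusters. Depth limits the rarest classes: mesenchymal cell-like libraries held 22 to 206 cells.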

Other observations

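All tests in this part were chosen after the data were seen. Choroid plexus-like libraries differed by their level of cytosolic ribosomal protein mRNA, which 6720 of 21772 genes followed. With that level as a covariate edgeR called 1051 genes for manganese (398 higher, 653 lower, 5210 at an unadjusted p under 0.05). All 1051 had the same direction without the covariate, 882 of them at an unadjusted p under 0.05 by edgeR. The libraries are the same in both fits, so this is no independent check. Genes of low oxygen and sugar uptake fell: NDRG1 by -1.45 ± 0.25 on the log2 scale (SE, n = 6 each, edgeR adjusted p = 0.020), SLC2A1 by -0.78 ± 0.14 (0.0212) and VEGFA by -0.62 ± 0.12 (0.0238). Of 41 hypoxia genes 7 were called lower and 1 higher. SREBF2 fell by -0.97 ± 0.16 and the innate signalling ligase TRAF6 by -0.88 ± 0.13 (edgeR adjusted p = 0.020 for both). So did ATP2C1, the Golgi calcium and manganese pump (-0.71 ± 0.18, 0.0471), and OPA1, which fuses mitochondrial inner membranes (-0.70 ± 0.14, 0.0237). TRMT10C and HSD17B10, of the mitochondrial tRNA processing complex, rose by 0.65 ± 0.11 and 0.91 ± 0.17 (edgeR adjusted p = 0.020 and 0.0219), with 8 of 51 mitochondrial ribosome genes called higher and 28 adjusted over the list alone. PSAT1 and PSPH of serine synthesis rose by 0.95 ± 0.22 and 0.78 ± 0.18 (edgeR adjusted p = 0.0374 and 0.0339) and the iron-binding acute phase protein LCN2 by 1.99 ± 0.44 (0.0315). The called genes that fell had a median span of 110741 bp and those that rose 10056 bp, against 28107 bp over all tested genes.

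Of 41 proteasome genes, chosen after their values were seen and so given without a test, 39 were higher in exposed organoids in astroglia-like cells (median log2 fold change 0.80), 37 in choroid plexus-like cells (0.32) and 36 over all cells (0.29), with 0 called by edgeR in each. Excitatory neuron-like cells, named by NEUROD2, NEUROD6 and BHLHE22, numbered 3912 in exposed and 46 in untreated organoids. They lay mostly in 3 exposed organoids, with 2490 in Mn replicate 20, 1156 in Mn replicate 8 and 260 in Mn replicate 12, so no test within this class could be run.

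Transcripts of long genes differed between organoids. Genes of at least 100000 bp took 15.9, 20.02 and 21.2% of UMIs in Con replicates 4, 5 and 14 and 7.34, 8.41 and 9.84% in Con replicates 1, 12 and 13, and 8.53 to 13.8% in exposed organoids. The long minus short gene level per organoid was the difference in mean log2 CPM, here with 1 CPM added and without TMM scaling. It was lower in exposed organoids by -0.86 in the TPH1 and RCVRN clusters, in 4 of 4 (two-sided exact permutation p = 0.0159, adjusted p = 0.0794), by -0.38 in astroglia-like cells (exact permutation p = 0.0519) and by -0.41 in choroid plexus-like cells (exact permutation p = 0.201), so none passed.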
